A study of Mus musculus with 383 samples.

How the data were processed

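Total RNA from 4 brain regions was measured on Affymetrix expression arrays of the mouse genome. The animals were males of the second generation (F2) of a cross between the inbred strains C57BL/6J and 129S1/SvImJ. The samples were 383 arrays from 117 mice, with 98 arrays of cortex, 83 of hippocampus, 94 of hypothalamus and 108 of thalamus. Of these mice, 51 had arrays of 4 regions, 50 of 3 regions, 13 of 2 regions and 3 of 1 region. A separate table held 283 sleep and behaviour traits of the same mice.

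The deposited expression values are on a log2 scale, made with affy and RMA per the submitters' processing notes, with no versions given in the sources used here. From the values themselves, each region had been normalised apart from the others. Cohort, which was the group of mice raised together, and hybridization date had also been taken out within each region before the values were deposited. Cohort explained a median of 1.46% of the variance of a probe set in cortex, where chance would give 8.25%, and 0.702% in thalamus, where chance would give 7.48%. About 0.2% of the values were missing, between 0.197% and 0.224% in the 4 regions, and were left missing in the linear models and set to the mean of the probe set elsewhere. Because cohort and date effects had been removed from the values while the tests did not know it, p-values can be somewhat too small. Values given with cohort or date taken out again are no check on these factors, since little of either was left to remove.

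The mean level of a probe set in hippocampus and hypothalamus did not lie on the usual log2 scale. In hippocampus 769 probe sets and in hypothalamus 335 had a mean outside the range from 0 to 16, against 0 in cortex and 0 in thalamus. Probe set means of cortex and thalamus correlated at r = 0.974 across probe sets, which are not independent replicates, and those of hippocampus and hypothalamus at r = 0.587. Differences between mice within a region were usable in all 4 regions, with a median SD of 0.218 in cortex, 0.249 in hippocampus, 0.226 in hypothalamus and 0.210 in thalamus. The log SD of probe sets correlated at r = 0.898 for cortex and thalamus and 0.914 for hippocampus and hypothalamus. Between these 2 pairs of regions r ran from 0.693 to 0.752. The spread of a single probe set, and a gap between mice, may thus not be on 1 scale in all 4 regions. Because of the means, a difference in level between regions was read as expression for cortex against thalamus only.

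The deposited trait values are, per the labels and the trait descriptions, of other units than expression, 1 scale for each trait: amounts, ratios to baseline, times and transformed scores. Many traits were on a transformed scale with values below 0, and cohort explained a median of 0.755% of their variance, where chance would give 7.27%, so the authors had transformed and adjusted them. The times of that adjustment and its tool are not given in the sources used here. Of the traits, 17 were picked from their descriptions before their values were read: 10 of sleep and 7 of affective behaviour. For recovery after deprivation and restraint the rule took the dark phase. A further 5 traits of the light phase were added after the data were examined.

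Probe sets were named with the platform's annotation and checked by gene ID against the reference gene table of assembly GRCm38.p6. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none, and 34741 of the single-gene probe sets had their gene ID in the reference table. This gave 18193 named genes, of which 9010 had several probe sets. Where 1 probe set per gene was needed, it was the one with the highest mean over all arrays. With the highest mean over cortex and thalamus arrays in its place, an alternative added after the data were examined, the probe set differed for 1473 genes. Gene positions were used only to tell which genes neighbour each other.

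Regions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with 1 mean per region over all 383 arrays. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 45037 probe sets with a log2 difference of at least 1. The same fit counted the probe sets higher in 1 region than in each of the other 3. The animal as a replicate block, the hybridization date as a term, arrays of a shared date only, quantile normalization of all arrays together, leaving out the lower 0.333 of probe sets by mean, leaving out arrays with an RNA integrity number (RIN) under 7, and no minimum difference were the alternatives chosen before the data were examined. A fit with cortex and thalamus arrays alone, with and without a new quantile normalization, was added after the data were examined.

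For gene lists, 27 were written before the data were examined: markers of the 4 regions, of tissues and cell types that a dissected sample could hold, and groups of signalling, clock, stress and housekeeping genes. Each list was tested with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation. Counts within a list are also given adjusted over the list alone.

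Expression was tested against each trait within a region by limma, with the trait brought to normal scores by rank and hybridization date as a factor. Adjustment was over all probe sets and all 17 traits of the region together, and slopes are log2 units per SD of the trait. The alternatives chosen at the same time were no date term, the date with most arrays only, cohort in place of date, RIN as a covariate, the trait as deposited, leaving out low probe sets, adjustment within each trait, and 5 principal components as covariates. Gene lists were tested against traits with camera over 1836 combinations of list, trait and region. The list score, which is the mean over members of the standardised values of a mouse, was added after the data were examined, with a permutation of mice.

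For pairs of regions, the correlation of each probe set over the mice with both arrays was computed after taking out date, with Benjamini-Hochberg adjustment over all probe sets and 100 matchings of the mice, the real one included. The pairing was checked first: the profile of a mouse correlated best with that of the same mouse in 62 of 69 mice for cortex and hippocampus, 78 of 80 for cortex and hypothalamus, 87 of 91 for cortex and thalamus, 65 of 67 for hippocampus and hypothalamus, 72 of 74 for hippocampus and thalamus and 85 of 88 for hypothalamus and thalamus. For 9 of the 10 genes with the highest correlation mice fell into separate clusters, so their values are given within clusters. A gene had separate clusters where the largest gap between neighbouring mice, with at least 6 mice on each side, exceeded the 99th percentile of 10000 simulated normal genes. That check was chosen after the data were examined, as were the list scores between regions, the tests of shared genes against traits, the comparison of deprivation with restraint and the closer look at immediate early genes.

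Trait pairs were tested over mice with Spearman's rho and Pearson's r and 100000 permutations, two-sided. Ratios of recovery to baseline were tested against 1 by flipping signs within mice, which is a paired permutation test with 100000 resamples. NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 in Python 3.11.15 were used.

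Named genes were chosen by rules written before the data were examined. They were the 6 genes per region with the largest smallest difference against the other 3 regions, the 5 genes with the smallest p per region among trait associations past the threshold, the 10 genes with the highest median correlation between regions, and 2 to 4 members of each list with the largest differences. After the levels of hippocampus and hypothalamus were seen, the first rule was applied instead to the 6 largest differences each way between cortex and thalamus. No trait association passed, so those named for traits were chosen after their values were seen.

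The region, trait and cross-region tests were tested on simulated data with the real design of arrays and mice. The list test was run on simulated values without hybridization dates. The region fit recovered 100% of 100 probe sets shifted by 1.5 log2 units, with 0 false calls among 45037. The trait scan, run on 45037 probe sets, recovered 71.6% of the probe sets tied to a trait with r = 0.5 in cortex, 50.7% in hippocampus, 50.7% in hypothalamus and 73.1% in thalamus, and 100% at r = 0.7. At r = 0.3 the same scan recovered only 4.48% in cortex, 4.48% in hippocampus, 0% in hypothalamus and 7.46% in thalamus. The test between regions recovered between 22.4% and 59.7% at r = 0.4, between 92.5% and 100% at r = 0.6 and 100% at r = 0.8. The list test with a preset correlation also called 69 of 200 lists of 16 correlated genes that had no tie to the trait, among 18193 genes, while the estimated correlation called 0 of 200. Both recovered 200 of 200 lists that had one, but the members of these lists shared nothing beyond the trait. How many lists of correlated genes with a tie the estimated correlation would miss was not simulated. The number of arrays limits the precision of each value.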

Results

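Gene expression was measured in cortex, hippocampus, hypothalamus and thalamus of 117 adult male F2 mice, together with traits of sleep and of anxiety- and depression-related behaviour of the same animals. Behaviour was tested from 7 weeks of age in the elevated plus maze, the open field, fear conditioning, tail suspension and forced swim. Electrodes for recording brain waves and muscle tone (EEG and EMG) were implanted at 10 weeks. Sleep was recorded at baseline, after 6 h of sleep deprivation and after 1 h of restraint, and tissue was taken at 16 weeks, between 6 and 7 h after lights on (ZT6 to ZT7). The median RNA integrity number was 7.7 in cortex, 8.9 in hippocampus, 9.2 in hypothalamus and 7.9 in thalamus. Per array, between 11 and 1026 of 45037 values were missing.

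Cortex and thalamus were compared to describe which transcripts set these regions apart. Among the genes higher in cortex, Tbr1, a transcription factor of glutamatergic cortical neurons, led with a log2 difference of 5.18 ± 0.07 (98 and 108 arrays). In this comparison ± gives the SE of the fit over all 4 regions, so the spread in hippocampus and hypothalamus enters it. Crym, which encodes a thyroid hormone binding protein, followed at 4.87 ± 0.07, then the dopamine D1 receptor gene Drd1 at 4.75 ± 0.05, the neuronal transcription factor Neurod6 at 4.71 ± 0.07, the receptor gene Gpr6 at 4.47 ± 0.05 and the immediate early gene Egr3 at 4.28 ± 0.05. Drd1 and Gpr6 are known for high expression in striatum. Among the genes higher in thalamus, the homeobox gene Shox2 led with a cortex minus thalamus difference of -7.34 ± 0.13.

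Next in thalamus were Slc6a3, the dopamine transporter gene of midbrain neurons, at -5.49 ± 0.08, and Tph2, which makes the enzyme that starts serotonin synthesis in raphe neurons, at -5.39 ± 0.05. The homeobox genes Lhx9 and Irx3 stood at -4.83 ± 0.05 and -4.72 ± 0.04, and the glycine receptor gene Glra1 at -4.61 ± 0.05. Each of these 12 genes differed in the same direction in all mice with both regions, which were between 88 and 91 mice per gene. Adjusted p-values from limma were at most 6.71e-187 for these genes. With no background values among the data used here, a low mean such as that of Shox2 in cortex (3.66) was not told from an absent signal.

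**Figure D1:**
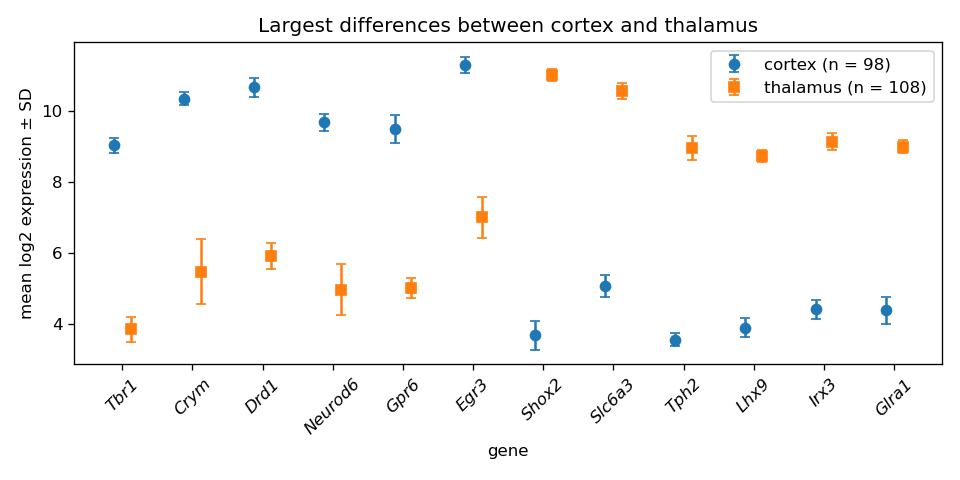
Mean log2 expression with SD of the 12 genes that differ most between cortex (98 arrays, circles) and thalamus (108 arrays, squares). Tbr1 averages 9.02 in cortex and 3.84 in thalamus, and Shox2 averages 3.66 in cortex and 11.0 in thalamus.

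Over all probe sets, 1036 were higher in cortex and 1444 were higher in thalamus, so 41.8% of 2480 called probe sets were higher in cortex. By gene, with 1 probe set each, 438 were higher in cortex and 788 in thalamus among 18193. With the animal as a replicate block 2469 were called, and with the arrays of the 1 hybridization date that held both regions (14 of cortex and 20 of thalamus) 2516 were called. The split by direction rests on the scaling: after quantile normalization of all arrays together 1953 were higher in cortex and 1472 in thalamus, and after that of cortex and thalamus arrays alone, added after the data were examined, 1397 and 947. The median over all probe sets was -0.145 in the deposited values, and -0.02 under both new scalings, and no probe set called before and after changed direction.

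Of 12 cortex markers, 8 were higher in cortex, with Fezf2, a transcription factor of deep-layer neurons, at 3.88 ± 0.04, Krt12 at 3.12 ± 0.12 and Mef2c at 2.81 ± 0.03, and 0 were lower (camera adjusted p = 1.81e-10, and adjusted p = 5.83e-06 with an estimated correlation). Of 12 thalamus markers, 10 were lower in cortex, with the transcription factor gene Tcf7l2 at -4.47 ± 0.04, the glutamate transporter gene Slc17a6 at -4.17 ± 0.05 and Synpo2 at -2.97 ± 0.06 (adjusted p = 3.48e-06, and adjusted p = 0.0579 with an estimated correlation). Of 13 hippocampus markers 2 were higher in cortex, of which Nptx1 at 1.17 ± 0.02 was the larger, and 3 were higher in thalamus, led by C1ql2 at -2.90 ± 0.04 and Dsp at -1.90 ± 0.08 (adjusted p = 0.60). Of 17 hypothalamus markers, 4 were higher in thalamus: Pmch, the gene of melanin-concentrating hormone, at -3.72 ± 0.10, Baiap3 at -2.38 ± 0.05, Otp at -2.04 ± 0.06 and Cartpt at -1.52 ± 0.05 (adjusted p = 0.390).

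Markers of neighbouring tissues differed as well. Of 8 striatum markers, 6 were higher in cortex samples, among them Drd1, Pde10a at 3.27 ± 0.03, Ppp1r1b, which encodes a phosphoprotein of striatal projection neurons, at 2.67 ± 0.03 and the enkephalin gene Penk at 1.93 ± 0.05 (adjusted p = 3.02e-11, and adjusted p = 0.00243 with an estimated correlation). Of 6 habenula markers, 4 were higher in thalamus samples: Pou4f1 at -3.23 ± 0.05, the nicotinic receptor genes Chrna3 at -3.14 ± 0.05 and Chrnb4 at -1.61 ± 0.05, and Gpr151 at -2.86 ± 0.06 (adjusted p = 0.0176, and adjusted p = 0.102 with an estimated correlation). Of 10 choroid plexus markers, 3 were higher in thalamus, led by Otx2 at -3.81 ± 0.11 and the transthyretin gene Ttr at -1.73 ± 0.22 (adjusted p = 0.982). Of 7 markers of meninges and mural cells, the matrix gene Dcn at -1.13 ± 0.06 and Igf2 at -1.07 ± 0.07 were higher in thalamus (adjusted p = 0.390), of which 1 was called after quantile normalization of all arrays and 0 after that of cortex and thalamus arrays alone. None of 6 pituitary markers (adjusted p = 0.803) or 3 blood markers (adjusted p = 0.919) was called by limma, with Tshb at -0.46 ± 0.05 and Hba-a1 at -0.57 ± 0.05 the largest.

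Among cell types of the brain, oligodendrocyte genes were lower in cortex. Of 9 measured, 5 were called, including the myelin genes Mag at -1.39 ± 0.03 and Mobp at -1.18 ± 0.02 and the lipid synthesis gene Ugt8a at -1.06 ± 0.03 (adjusted p = 0.000537, and adjusted p = 0.245 with an estimated correlation), and after quantile normalization of cortex and thalamus arrays alone 2 were. Of 10 astrocyte markers, Gfap at -1.32 ± 0.04 and S100b at -1.15 ± 0.02 were lower in cortex (adjusted p = 0.0598). Of 4 oligodendrocyte precursor markers, Bcas1 was lower at -1.11 ± 0.02 (adjusted p = 0.803), and 0 were called after quantile normalization of cortex and thalamus arrays alone. The microglia list was higher in cortex (adjusted p = 0.00146, and adjusted p = 0.102 with an estimated correlation) with 0 of 9 members past the minimum difference, Aif1 at 0.78 ± 0.03 and Cx3cr1 at 0.62 ± 0.02 being the largest. No neuron marker of 10 (adjusted p = 0.390) and no endothelium marker of 9 (adjusted p = 0.329) passed that minimum, with Tubb3 at -0.87 ± 0.02 and Vwf at -0.84 ± 0.04 the largest.

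Immediate early genes, which neurons transcribe when active, were higher in cortex. Of 16, 8 were called, all higher, among them Egr3, Egr2 at 2.20 ± 0.08, Homer1 at 2.01 ± 0.02 and Nr4a1 at 1.60 ± 0.05 (adjusted p = 3.88e-09, and adjusted p = 0.0337 with an estimated correlation). Of 20 glutamate receptor and transporter genes, 7 were higher in cortex, led by the vesicular transporter Slc17a7 at 3.23 ± 0.06, Grik2 at 1.61 ± 0.04 and Gria3 at 1.56 ± 0.02, and Grin2d was lower at -1.28 ± 0.02 (adjusted p = 1.22e-05, and adjusted p = 0.00262 with an estimated correlation). Of 13 genes of GABA signalling, the receptor subunits Gabra2 at 1.86 ± 0.06, Gabra3 at 1.38 ± 0.04 and Gabrd at 1.36 ± 0.05 were higher (adjusted p = 0.0335, and adjusted p = 0.156 with an estimated correlation). The stress axis list had Crh, the corticotropin-releasing hormone gene, at 1.84 ± 0.05 and its binding protein Crhbp at 1.41 ± 0.03 higher, and Tsc22d3 at -1.21 ± 0.02 and Hsd11b1 at -1.15 ± 0.03 lower, of 14, with 1 lower after quantile normalization of cortex and thalamus arrays alone (adjusted p = 0.0217, and adjusted p = 0.0641 with an estimated correlation). With hybridization date as a term, the GABA and stress axis lists had adjusted p = 0.0647 and adjusted p = 0.0561.

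Of 19 monoamine genes, Drd1 was higher in cortex and 4 were higher in thalamus, including Slc6a3, the vesicular transporter Slc18a2 at -3.64 ± 0.04 and the serotonin transporter Slc6a4 at -3.63 ± 0.05 (adjusted p = 0.452), while under either new quantile normalization 3 were higher in each. Of 14 sleep and arousal genes, the muscarinic receptor Chrm1 was higher at 2.68 ± 0.03, and Pmch and the orexin receptor Hcrtr1 at -2.40 ± 0.04 were lower (adjusted p = 0.803). Npas2 at 1.62 ± 0.06 was the 1 core clock gene called of 16 (adjusted p = 0.208), and Hspa1b at 1.18 ± 0.05 the 1 chaperone of 13 (adjusted p = 0.202). Cholesterol synthesis genes were lower in cortex as a list (adjusted p = 0.0102, and adjusted p = 0.198 with an estimated correlation), with 0 of 11 called and Insig1 at -0.76 ± 0.02 and Dhcr7 at -0.72 ± 0.02 the largest. Complex I subunits of the respiratory chain were lower too (adjusted p = 1.18e-06, and adjusted p = 0.0758 with an estimated correlation), with 0 of 34 called, Ndufa6 at -0.80 ± 0.01 and a list median of -0.41, against -0.26 under either new quantile normalization and a median of -0.145 over all probe sets as deposited. Among 43 ribosomal protein genes, Rps4l was called at -1.24 ± 0.04 (adjusted p = 0.0335, and adjusted p = 0.512 with an estimated correlation).

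In all, 13 of the 27 lists passed camera with the preset correlation and 4 with an estimated correlation: cortex markers, striatum markers, immediate early genes and glutamate receptors. Counted adjusted over the list alone, the same number of members was called in each list. For the choroid plexus, hippocampus, pituitary, core clock, chaperone, and sleep and arousal lists camera gave a direction opposite to the median of the list, and none of these passed.

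The other 5 contrasts could not be read as expression, because of the levels of hippocampus and hypothalamus. Cortex differed from hippocampus in 25763 probe sets and from hypothalamus in 26670. Hippocampus differed from hypothalamus in 27836 and from thalamus in 26612, and hypothalamus from thalamus in 25468. As designed, 109 probe sets were highest in cortex, 7200 in hippocampus, 9005 in hypothalamus and 173 in thalamus.

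Regions of the same mice were compared to describe which transcripts vary between animals in all 4 regions together. For Pttg1, which encodes securin, an inhibitor of chromosome separation, 29 of 117 mice formed a lower cluster with mice from 9 of 9 cohorts. The higher cluster lay above it by between 3.16 log2 units in thalamus and 3.68 in cortex (largest SE 0.22). The lower cluster held 31 mice for Galc, which encodes an enzyme of myelin lipid breakdown (2.83 to 3.83 log2 units lower), and 30 for the phospholipid enzyme gene Gdpd3 (2.73 to 3.84). It held 27 for Tia1, which encodes an RNA-binding protein of stress granules (2.66 to 3.66), 22 for the palmitoyltransferase gene Zdhhc14 (1.11 to 2.93) and 27 for Prdx2, which encodes a peroxide-removing enzyme (2.51 to 2.98). It held 34 for Dzip1, which encodes a protein of the primary cilium (3.22 to 3.86), 30 for the cell death gene Xaf1 (3.57 to 4.48) and 34 for the phosphatase gene Mtmr7 (2.53 to 4.96). For Adi1, of the methionine salvage pathway, the largest gap was 0.367 SD against the threshold of 0.450 SD, so separate clusters were not called. Split at that gap, 35 mice still lay lower than the others by 1.46 to 3.03 log2 units (largest SE 0.13). The clusters were drawn from the values themselves, so these gaps carry no test. Each gap is that of 1 probe set. Of the probe sets of a gene, 3 of 3 correlated in all 6 pairs of regions for Pttg1 and Adi1. For Prdx2, Xaf1 and Mtmr7 2 of 2 did, and Gdpd3 had only 1. For Zdhhc14 2 of 6 did, for Galc 1 of 3, for Dzip1 1 of 5 and for Tia1 1 of 6. In these last 4 genes the gap is not read as one of the whole transcript level.

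The 9 genes with separate clusters and Adi1 were chosen for their high median correlation between regions in these same mice. The clusters were drawn from the same values as well. The p-values given here for these genes are therefore no separate support for a correlation. Within the higher cluster the 9 genes with separate clusters correlated between regions, and no pooled r is given for them. Over the 6 pairs of regions, the median Pearson r ran from 0.629 for Dzip1 to 0.794 for Pttg1 (46 to 74 mice per pair) and the median Spearman rho from 0.614 to 0.773. All 6 pairs of each gene had p of at most 0.0001 (20000 permutations), and the median r without the 2 mice farthest from the median ran from 0.601 to 0.778. In the lower cluster (11 to 27 mice per pair) the median r was 0.794 for Pttg1, with unadjusted p under 0.05 in 6 pairs. It was 0.590 for Zdhhc14 with 4 such pairs, 0.576 for Dzip1 with 4, and 0.201 for Gdpd3 with 0. For Adi1, over all mice of a pair (67 to 91), the median r was 0.955 (0.931 to 0.970) and the median rho 0.904 (0.857 to 0.932), with adjusted p of at most 1e-05 over the 6 pairs, the smallest that 100000 permutations can give. Its lowest r was 0.927 without the 2 mice farthest from the median and 0.955 on the hybridization dates with most arrays (at least 55 mice). With cohort taken out again it was 0.938, which is no check on cohort. Split at its largest gap, the median r was 0.501 in the lower mice (16 to 27 per pair, unadjusted p under 0.05 in 3 pairs). In the higher mice (51 to 65 per pair) it was 0.790, so the r over all mice also holds the gap between these groups.

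**Figure D2:**
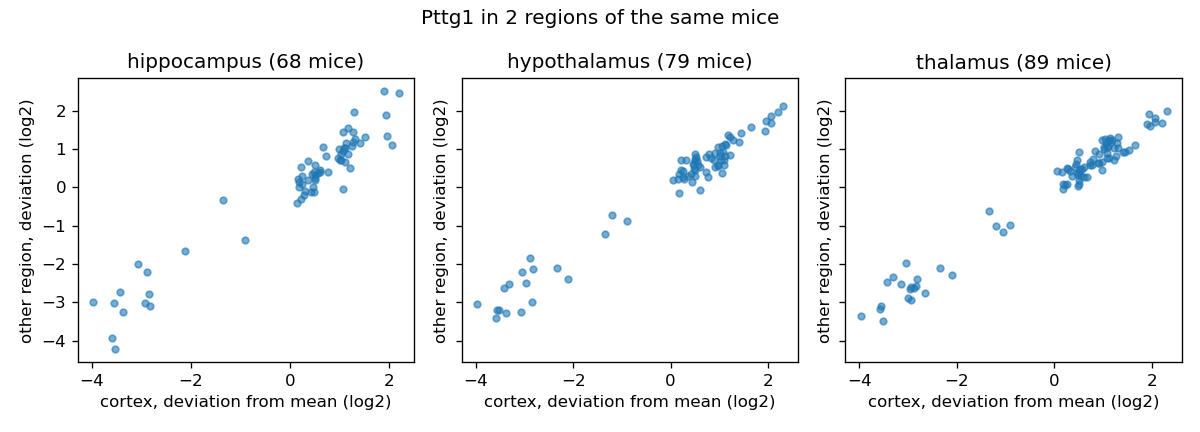
Level of Pttg1 in each mouse, as log2 deviation from the mean of its region, in pairs of regions. The lower cluster holds 29 of 117 mice, of which 14 to 22 were measured in both regions of a pair.

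Over all probe sets, 3849 correlated between cortex and thalamus (91 mice), of which 3796 were positive. For hippocampus and hypothalamus 3768 passed (3720 positive, 67 mice), for hypothalamus and thalamus 3546 (3444 positive, 88 mice) and for cortex and hypothalamus 2958 (2882 positive, 80 mice). For hippocampus and thalamus 2600 passed (2500 positive, 74 mice), and for cortex and hippocampus 2474 (2391 positive, 69 mice). In all 6 pairs, 1428 probe sets of 932 genes passed, and of these probe sets 1340 did so with cohort taken out again and 931 with 5 principal components removed. Separate clusters of mice were found for 50 of the 932 genes, with the smaller cluster the lower one for 48 of them and holding a median of 24.8% of mice. Members of the lists among the 932 genes were the immediate early genes Fos and Dusp1, the clock genes Npas2 and Per3, the chaperone genes Hspa1b, Hspa5, Hspa8 and Pdia6, the myelin genes Mbp and Opalin, and the astrocyte gene Gfap. The others were Alas2, Uchl1, Gabra2, Grik1, Hmgcs1, Sc5d, Rpl22, Rps25, Rps4l, Rps6, Rps9, Ndufa12, Ndufc2 and Ndufs5.

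As scores, which average the standardised members of a list in a mouse, chaperones went together most between regions. Their median Pearson r over the 6 pairs was 0.686 (0.626 to 0.788) and their median Spearman rho 0.577, with p of at most 1e-05 in every pair, the smallest that 100000 permutations can give. Immediate early genes followed with a median r of 0.530 (0.359 to 0.798, largest p = 0.00178) and rho of 0.530, microglia genes with 0.508 (0.312 to 0.557, largest p = 0.00707) and 0.466, and cholesterol synthesis genes with 0.448 (0.379 to 0.505, largest p = 0.00021) and 0.396. After adjustment over 162 pairs of scores, 39 passed, among them all 6 pairs of each of these 4 lists (largest adjusted p = 0.0324). Without the 2 mice farthest from the median the lowest r was 0.529 for chaperones, 0.348 for immediate early genes, 0.278 for microglia and 0.342 for cholesterol synthesis. On the hybridization dates with most arrays (at least 55 mice) it was 0.665, 0.408, 0.297 and 0.342. With cohort taken out again it was 0.618, 0.367, 0.307 and 0.377, which is no check on cohort, since cohort had been removed before deposit. Scores of striatum markers (median r = -0.0906) and of choroid plexus markers (median r = -0.0645) passed in 0 pairs. These scores were examined after the data were seen. Of 13 chaperones, 4 passed on their own in all 6 pairs, and members had a mean pairwise r of only 0.0935 to 0.191 within a region. On their own, 2 of 16 immediate early genes, 2 of 11 cholesterol synthesis genes and 0 of 9 microglia genes passed in all 6 pairs. How far such single members carry the scores was not tested.

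Sleep after deprivation and restraint was compared with baseline in the same mice, as the ratio of recovery to baseline. After deprivation, wake in the last 4 h of the light phase (ZT8 to ZT12) fell to a mean of 0.743 ± 0.113 of baseline (SD, 111 mice, below 1 in 109; adjusted p = 2e-05). The unadjusted p, 1e-05, is the smallest these permutations can give. NREM delta power, the slow-wave activity of non-REM sleep that builds up with time awake, rose to 1.16 ± 0.0509 in the same hours and was above 1 in 111 of 111 mice (adjusted p = 2e-05). The share of REM sleep was 0.963 ± 0.228 (below 1 in 65 of 111; adjusted p = 0.0872). That call depends on the test: the share passed by Wilcoxon (adjusted p = 0.0214) and without the 2 extreme mice (adjusted p = 0.00783). With cohorts weighted equally it did not pass (adjusted p = 0.0728). In the first dark hours (ZT12 to ZT16) wake fell to 0.828 ± 0.117 (below 1 in 103 of 111; adjusted p = 2e-05) and delta power to 0.990 ± 0.0422 (below 1 in 70 of 109; adjusted p = 0.0194).

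After restraint, wake in the 6 h left of the light phase (ZT6 to ZT12) rose to 1.13 ± 0.183 of baseline (70 mice, above 1 in 59; adjusted p = 2e-05). NREM sleep fell to 0.948 ± 0.122 (below 1 in 56; adjusted p = 0.000707), REM sleep to 0.890 ± 0.215 (below 1 in 52; adjusted p = 7.5e-05) and the REM share to 0.952 ± 0.183 (below 1 in 44; adjusted p = 0.0302), while delta power rose to 1.02 ± 0.0315 (above 1 in 49; adjusted p = 5.14e-05). In the dark phase (ZT12 to ZT18) wake fell to 0.819 ± 0.125 (below 1 in 67 of 70; adjusted p = 2e-05) and delta power to 0.965 ± 0.0452 (below 1 in 53 of 68; adjusted p = 2e-05). Cohort means of wake after deprivation ran from 0.735 to 0.750 in the light phase, and those of wake after restraint from 1.11 to 1.17. The ratios had been adjusted before they were deposited, so close cohort means are no separate support. What the adjustment did to the means over all mice is not known.

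**Figure D3:**
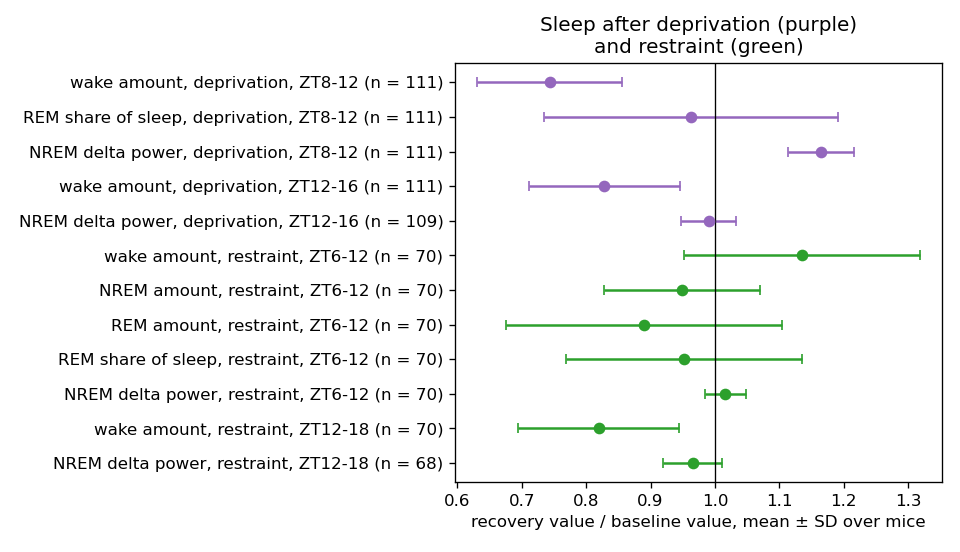
Recovery as a ratio to baseline, mean with SD over mice, after sleep deprivation and after restraint. Wake amount after deprivation averages 0.743 and after restraint 1.13 in the light phase.

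Sleep and affective behaviour were compared over mice in 70 pairs of traits, to describe whether they vary together between animals. None passed by Spearman permutation, with the smallest adjusted p at 0.345, and 5 had an unadjusted p under 0.05 by Spearman and 6 by Pearson. By unadjusted p alone, mice with more baseline delta power rested less in the forced swim test (rho = -0.280, p = 0.0102, and r = -0.242, p = 0.0265, in 84 mice). Without the 2 mice farthest from the median rho was -0.254. With cohort taken out again it was -0.278. The traits had been adjusted before deposit, so values with cohort taken out again are no check on cohort. Mice with a higher trait value for NREM sleep after deprivation in the dark had a higher trait value for open field distance (rho = 0.236, p = 0.0141, and r = 0.309, p = 0.00137, in 107 mice). Here rho was 0.245 with cohort taken out again and 0.211 without the 2 farthest mice. The NREM trait is on a transformed scale and ran against baseline NREM amount (rho = -0.505), so a higher value is not read as more sleep. Mice with a higher trait value for NREM bout number froze more to the cue (rho = 0.244, p = 0.0148, and r = 0.261, p = 0.00875, in 100 mice). There rho was 0.241 with cohort taken out again and 0.233 without the 2 farthest mice. Open field distance and NREM bout number are on transformed scales too, so their values are not read as amounts.

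Among traits of 1 class, 12 of 45 sleep pairs and 2 of 21 affective pairs passed by Spearman, adjusted over 66 pairs, in a comparison added after the data were examined. The transformed trait values of open arm time in the plus maze and distance in the open field went together (rho = 0.393, adjusted p = 0.00011, and r = 0.401, adjusted p = 0.000132, in 117 mice). So did contextual and cued freezing (rho = 0.280, adjusted p = 0.0207, and r = 0.299, adjusted p = 0.0107, in 106 mice). Without the 2 mice farthest from the median r was 0.403 and 0.274, and with cohort taken out again 0.410 and 0.298. Baseline wake and NREM amounts, which share 1 day, were nearly opposite (rho = -0.975; r = -0.982; 111 mice).

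Expression was tested against 17 traits within each region, and no gene passed by limma over all traits of a region. At unadjusted p under 0.05 there were 39700 pairs of probe set and trait in cortex (5.19% of 765629), 43504 in hippocampus (5.68%), 45388 in hypothalamus (5.93%) and 46258 in thalamus (6.04%). An unmoderated test on the same data gave 39599, 43455, 45175 and 46014, and 29, 2, 1 and 1 of 100 orders of the mice, the real one included, had as many. Adjusted within each of the 17 traits, 13 associations passed over the 4 regions. The sign of a slope refers to the deposited trait value, which was transformed for open arm time, open field distance, centre time and NREM bout number. In hypothalamus Npvf, the gene of a neuropeptide that acts on reproduction and stress, went with open arm time (slope -0.19 ± 0.03 log2 units per SD of the trait, 94 mice). Poldip2 (-0.04 ± 0.01) and the neuropeptide precursor gene Vgf (0.05 ± 0.01) went with the ratio of delta power after deprivation to baseline (dark phase, 87 mice). The myosin gene Myh9 went with cued freezing (0.09 ± 0.02, 86 mice). Over all traits the adjusted p of these hypothalamus genes was between 0.167 and 0.30.

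In thalamus the signalling inhibitor gene Smad6 went with NREM bout number (-0.13 ± 0.02, 102 mice), Ndrg2, an astrocyte gene, with baseline REM sleep (-0.03 ± 0.01, 102 mice) and the kinase gene Phkg1 with centre time in the open field (-0.08 ± 0.02, 108 mice). Chil1 (-0.09 ± 0.02), Armc9 (-0.17 ± 0.03) and Lypd1 (0.17 ± 0.03) went with open field distance (108 mice). Over all traits the adjusted p was 0.253 for the first 3 and 0.293 for the others. In hippocampus Rpe (-0.16 ± 0.03) and Tmem71 (0.21 ± 0.04) went with NREM bout number (78 mice; over all traits adjusted p = 0.299 and 0.350), and in cortex Fam149b with baseline REM sleep (-0.08 ± 0.01, 94 mice; over all traits adjusted p = 0.397). Among the 5 traits added after the data were examined, 8 probe sets passed within the NREM and 1 within the REM ratio to baseline after restraint in hippocampus (light phase, 41 mice). Tmem40 at 0.27 ± 0.04 and the kinase gene Ptk2b at -0.09 ± 0.01 led with the NREM ratio. In thalamus 2 passed within the delta power ratio to baseline and 2 within the transformed trait of REM sleep after deprivation (light phase, 102 mice). Among them were Smad6 at -0.12 ± 0.02 and the catalase gene Cat at -0.09 ± 0.02. The genes named here were chosen after their values were seen. The 932 genes shared between regions were tested against 22 traits as well, and none passed after adjustment over the traits, with Chil1 and open field distance the closest (family-wise p = 0.0053, adjusted p = 0.117). Adjusted within a trait, 9 of these genes passed for cued freezing, 8 for baseline NREM amount, among them Eps8, 7 for open field distance and 2 for baseline wake amount. Genes of this set 1 to 10 Mb apart had a median absolute r of 0.755 over mice. Such a count may therefore hold neighbouring genes that vary together, and is not a number of separate associations.

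Gene lists were tested against the same traits, to describe whether groups of genes vary with sleep or behaviour. In cortex, immediate early genes had positive slopes with baseline NREM delta power (camera adjusted p = 2.57e-20, and adjusted p = 0.482 with an estimated correlation). All 16 slopes were positive with a median of 0.10 log2 units per SD of the trait (94 mice), and 14 passed adjusted over the list alone. This combination was picked for its smallest p, and its members went together between mice (mean pairwise r = 0.494). The counts of members are therefore no separate support. Over all traits of the region, the adjusted p from limma was between 0.872 and 0.976 for the members. The largest were Egr2 at 0.30 ± 0.08, Fos at 0.24 ± 0.07, Arc, whose product acts at synapses, at 0.22 ± 0.07 and Nr4a1 at 0.14 ± 0.05, and the growth factor gene Bdnf had 0.09 ± 0.02. Fosb at 0.05 ± 0.03 and Homer1 at 0.02 ± 0.01 did not pass.

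Choroid plexus genes in hippocampus samples had negative slopes with the transformed trait of REM sleep after deprivation in the dark. Slc4a5 had -0.44 ± 0.19 and the transthyretin gene Ttr -0.33 ± 0.12 (camera adjusted p = 2.81e-07, and adjusted p = 0.914 with an estimated correlation, 72 mice). Of these choroid plexus genes, 0 of 10 passed adjusted over the list alone. Their slopes with baseline delta power were positive, with the folate receptor gene Folr1 at 0.39 ± 0.15 and Ttr at 0.31 ± 0.12 (camera adjusted p = 2.81e-07, and adjusted p = 0.914 with an estimated correlation; 3 of 10 passed adjusted over the list alone; 78 mice). Oligodendrocyte genes in cortex had positive slopes with the transformed trait of NREM sleep after deprivation in the dark, which is not read as an amount. Ugt8a had 0.07 ± 0.02, Ermn 0.07 ± 0.02 and Mobp 0.04 ± 0.02 (camera adjusted p = 2.81e-07, and adjusted p = 0.914 with an estimated correlation, 92 mice). Of 9 members, 4 passed adjusted over the list alone. These combinations too were picked for their small p, so counts of members that passed are no separate support.

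Of 1836 combinations of list, trait and region, 113 passed with the preset correlation: 31 in cortex, 38 in hippocampus, 22 in hypothalamus and 22 in thalamus. With an estimated correlation 0 passed, and 21, 25, 19 and 11 had an unadjusted p under 0.05. By list, choroid plexus passed in 16, oligodendrocytes, meninges and mural cells, and immediate early genes in 10 each, thalamus markers and endothelium in 8 each and complex I in 7. Microglia, cholesterol synthesis and ribosomal proteins passed in 6 each, hypothalamus markers, striatum and chaperones in 5 each, cortex markers in 4, hippocampus markers and the core clock in 3 each, and glutamate receptors in 1. Habenula, pituitary, blood, neurons, astrocytes, oligodendrocyte precursors, the stress axis, monoamine genes, GABA receptors, and sleep and arousal signals passed in 0, with smallest adjusted p between 0.0529 and 0.162.

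The score of immediate early genes was then set against baseline delta power, after the data were examined. In cortex the Pearson r was 0.405 (95% interval 0.221 to 0.562, p = 8e-05, adjusted over 4 regions 0.00032) and Spearman rho 0.401 (p = 0.00011, 94 mice). Without the 2 mice farthest from the median r was 0.380 (p = 0.0002), and on the hybridization date with most arrays 0.443 (p = 0.00011, 74 mice). The r was positive in 8 of 9 cohorts and ran from -0.458 to 0.605. In hippocampus r was 0.0347 (p = 0.764, 78 mice), in hypothalamus 0.142 (p = 0.186, 89 mice) and in thalamus 0.158 (p = 0.111, 102 mice), with rho 0.0849, 0.194 and 0.157. In mice with both regions the r in cortex was higher by 0.251, 0.230 and 0.119 (p = 0.0465, 0.0173 and 0.0990), and after adjustment none passed (adjusted p = 0.0698, 0.0520 and 0.0990). Adjusted over all 1836 combinations, the score with ranked delta power had r = 0.397 and adjusted p = 0.0734.

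**Figure D4:**
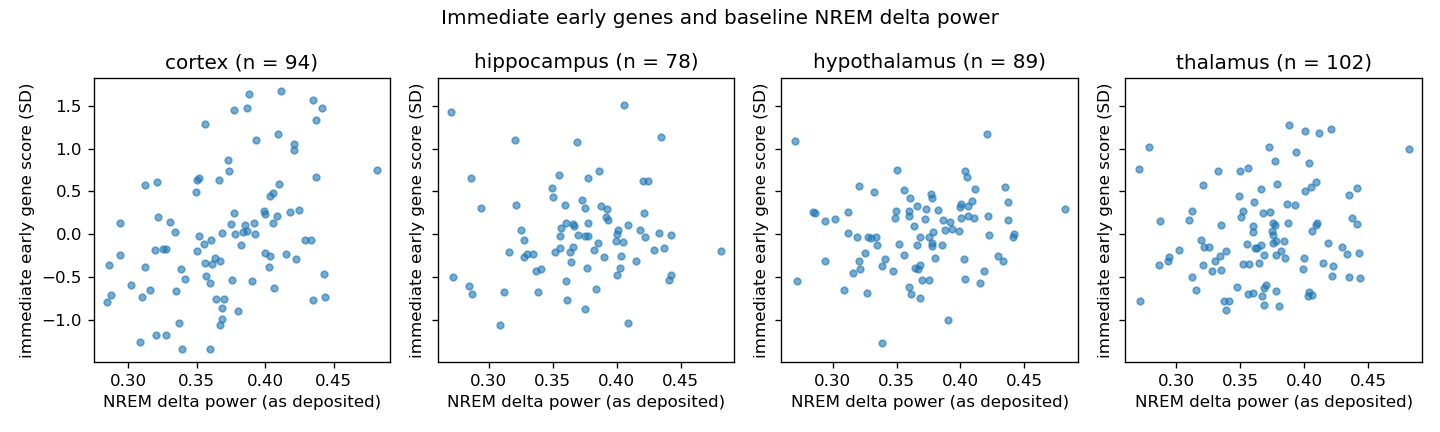
Score of 16 immediate early genes in each mouse against its baseline NREM delta power, by region. The Pearson r is 0.405 in cortex, 0.0347 in hippocampus, 0.142 in hypothalamus and 0.158 in thalamus.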

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

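The comparison of deprivation with restraint and the tests of region labels, of mouse matching, of cohort and date, of unit, of the direction of shifts in level, of RNA quality and of the share of cortical neurons were chosen only after the results were seen.

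Recovery differed between deprivation and restraint in mice that went through both. The wake ratio in the light phase was lower after deprivation by a mean of -0.388 (0.748 against 1.14, lower in 66 of 67 mice, adjusted p = 2.5e-05). The NREM delta power ratio was higher after deprivation by 0.144 in the light phase (1.16 against 1.02, higher in 67 of 67 mice, adjusted p = 2.5e-05) and by 0.0238 in the dark phase (0.991 against 0.967, higher in 44 of 63 mice, adjusted p = 0.00112). The REM share in the light phase (p = 0.436) and wake in the dark phase (p = 0.417) did not pass. The recording windows of deprivation and restraint differ in length, so their share in these differences was not tested.

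Chance was tested by shuffling the region labels within mice. In each test 1 of 100 arrangements, the real one, gave as many calls. Where hippocampus or hypothalamus took part, their levels alone can give this outcome, so it says nothing on expression. For cortex and thalamus, the shuffles moved hippocampus and hypothalamus arrays into both groups. The shuffled count is therefore no clean reference for that contrast, and no conclusion is drawn from it. The real counts were 25763 probe sets for cortex and hippocampus (highest of the others 6261), 26670 for cortex and hypothalamus (3080), 2480 for cortex and thalamus (1072), 27836 for hippocampus and hypothalamus (5156), 26612 for hippocampus and thalamus (3906) and 25468 for hypothalamus and thalamus (2423). Probe sets highest in 1 region were 16487 (1420), while gene lists were 13 against 12, too close for their number to say more.

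Genes such as Pttg1, Galc and Mtmr7 went together between regions of the same mice, in all 6 pairs for 1428 probe sets. Chance matching is excluded, since 1 of 100 matchings, the real one, gave as many, and the highest of the others in any pair was 1. Shared cohort or date was not tested: 93.8% of the probe sets passed in all 6 pairs with both taken out, but both had been removed from the deposited values already. Inherited variation near the genes is a candidate explanation: genes 1 to 10 Mb apart had a median absolute r of 0.755 against 0.0680 on different chromosomes, a ratio of 11.1 (highest of 99 shuffles 1.06). A strain difference in the sequence under single probe sets would give the same linkage and cannot be told apart, because other probe sets of the same genes passed 3.51 times as often as probe sets at large, with an interval from 2.99 to 4.07 that reaches below the bound of 3, and 554 of 684 genes had no other probe set that passed.

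Probe set means in hippocampus and hypothalamus lay far outside the range of cortex and thalamus. The means ran from -12.6 to 29.3 in hippocampus and from -6.30 to 18.1 in hypothalamus, against 2.96 to 14.6 in cortex. Levels outside the usual log2 range from 0 to 16 argue against true differences in transcript level as the whole cause. On average over genes, 71.1% of the other probe sets of the same genes shifted against cortex in the same direction (interval 67.4% to 74.6%). This lay between the bounds of 60% and 80% set for the test, so a part played by true differences stays open. The percentage was 79.8% in hippocampus (interval 75.9% to 83.6%) and 48.9% in hypothalamus (interval 41.9% to 55.9%). This split by region was made without a bound of its own, and probe sets that differed between cortex and thalamus had 87.4%. Another unit or log base is argued against by the spread between mice, whose median was at most 1.14 times that of cortex. An error in the level of each probe set that scales with its spread stays open, with a rank correlation between the shift and the SD of 0.146 in hippocampus and 0.0122 in hypothalamus, against 0.0273 for cortex and thalamus.

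Immediate early genes such as Egr2, Fos and Arc went with baseline NREM delta power in cortex. RNA quality and the share of striatal tissue in the cortex sample are argued against, since r kept 97.8% and 98.1% of its value with each taken out. Cohort and date were not tested, since both had been removed before deposit and taking them out again left 103%. The share of cortical neurons stays open, since r kept 92.8% with the score of cortex markers taken out (interval 75.2% to 108%). That score had r = 0.320 with ranked delta power (unadjusted permutation p = 0.00156), which did not pass over all 1836 combinations (adjusted p = 0.724). Selection from many combinations stays open: the largest of all combinations of list, trait and region was matched in a share of 0.127 of shuffles of the mice. The pattern may therefore be a product of the number of combinations, and a tie between recent cortical activity and sleep intensity was not tested in other animals.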

How the results depend on the processing

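The tests on cortex and thalamus arrays alone, of another probe set per gene, of the added traits, of list scores and of the immediate early gene score under covariates were chosen only after the results were seen, and all other alternatives before.

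Among alternatives for counts, 111 stayed within 1.5 times the reported count and 18 did not. With the animal as a replicate block the counts were 25779 for cortex and hippocampus, 26657 for cortex and hypothalamus, 2469 for cortex and thalamus, 27834 for hippocampus and hypothalamus, 26600 for hippocampus and thalamus and 25468 for hypothalamus and thalamus, with 16491 highest in 1 region and 13 lists. Over the alternatives that stayed, cortex and thalamus ran from 2273 to 3425 and lists from 12 to 13. Tbr1 ran from 5.16 to 6.53 log2 units and Shox2 from -8.68 to -7.31. No date held both regions for cortex and hippocampus, hippocampus and thalamus, or hypothalamus and thalamus, so the shared-date alternative could not be run there.

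Without a minimum difference, the counts were 43634, 43735, 37957, 43124, 43782 and 43691 in the same order of contrasts, because smaller differences are then counted. Leaving out the lower probe sets gave 17648 for hippocampus and thalamus, with fewer probe sets tested. With an estimated correlation 4 lists between regions passed, and the cause was not tested. Of the lists against traits 0 passed with it and 0 as list scores with permutation of mice, against 106 with cohort and 114 with RIN, and in simulated lists of correlated genes without a tie the preset correlation called 69 of 200 and the estimated one 0.

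Adjustment within each trait gave 1 association in cortex, 2 in hippocampus, 4 in hypothalamus and 6 in thalamus, because fewer tests are then adjusted together. The 5 added traits gave 3 in hippocampus, and 5 principal components as covariates 1 in hypothalamus, and the cause was not tested. All other alternatives for traits gave 0. With 5 principal components removed, correlated probe sets fell from 3768 to 2393 for hippocampus and hypothalamus and from 2600 to 1706 for hippocampus and thalamus, and the cause was not tested.

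The REM share after deprivation (ZT8 to ZT12) passed by the Wilcoxon test (median 0.947, adjusted p = 0.0214) and without the 2 extreme mice (mean 0.948, adjusted p = 0.00783), and not with cohorts weighted equally (adjusted p = 0.0728). The r of the immediate early gene score with delta power in cortex ran from 0.376 to 0.443. No background or detection values are among the data used here, so a low signal could not be told from an absent one.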

Other observations

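No test of this part was planned before the data were examined.

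Some genes varied strongly between mice within a region. In hypothalamus samples the pituitary hormone gene Cga had an SD of 2.32 log2 units over 94 mice, the largest of the named genes there, and in cortex samples Ttr, of the choroid plexus, had an SD of 1.97. In hippocampus samples 10 choroid plexus genes had a mean pairwise r of 0.868, with Slc4a5 varying most (SD 1.77, 83 mice). Striatum genes in cortex samples had a mean pairwise r of 0.799, with Drd2 varying most (SD 0.342), and oligodendrocyte genes 0.806 in hippocampus and 0.580 in cortex. Between regions of the same mice, striatum scores (median r = -0.0906) and choroid plexus scores (median r = -0.0645) did not go together. Prune2 (SD 2.28 in cortex and 2.27 in thalamus) and Psmd6 (2.06 and 2.34) varied strongly in both of these regions.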
